A study of Mus musculus with 6 samples.

How the data were processed

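RNA was measured by bulk sequencing of kidneys from wild-type C57BL/6 mice aged 6 to 8 weeks, 24 h after an intraperitoneal injection of lipopolysaccharide (LPS, 3 mice) or phosphate-buffered saline (Control, 3 mice), per the labels and the series' design text. Total RNA was extracted with TRIzol and made into libraries with a VAHTS Universal V6 kit, per the labels' protocols.

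The authors deposited a raw count per gene symbol and an FPKM value per gene symbol for each of the 6 libraries. HISAT2, HTSeq, SAMtools, DESeq2 and R 3.2.0 are named, per the submitters' processing notes, with no role or order. The genome build, the gene annotation, the strand setting of the counting and the tool that made the FPKM values are not given in the sources used here, so no coordinates are printed. All libraries list the same 17680 gene symbols, each with at least 1 count in the 6 libraries together, and 17413 of them (98.5%) are protein-coding genes in the RefSeq table of mouse assembly GRCm38.p6. Symbols found there, of any gene type, numbered 17558. The deposited FPKM values equal the deposited count divided by a whole-number gene length and the library's summed counts in all 106080 values compared, within a relative tolerance of 1e-06. Mitochondrially encoded genes, Xist, Mx1, Mx2 and a few other symbols of the gene lists were not analysed here.

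Groups were taken from the sample titles. The counts were tested with edgeR 4.0.16 in R 4.3.3: genes were kept by filterByExpr at its defaults (a minimum count of 10 and a minimum total of 15), scaled by TMM factors and tested two-sided for LPS against Control with the quasi-likelihood test. All adjusted p-values of single genes are Benjamini-Hochberg values of that test over the 14219 genes kept, with 0.05 as the threshold. The filter removed 3461 genes. The standard error (SE) of a log2 fold change is the fold change divided by the square root of the quasi-likelihood F statistic. Expression levels are CPM, counts scaled to a common library size with the TMM factors, as mean ± SD over 3 libraries, unless said to be unscaled.

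The comparison, the tests, 36 gene lists, the rule for named genes and the alternatives were fixed before the data were examined. Lists with at least 3 tested members were tested with camera in limma 3.58.1 on log2 CPM (prior count 2), with a preset inter-gene correlation of 0.01 and Benjamini-Hochberg adjustment over 34 lists. The rule named the 12 genes with the largest and the 12 with the smallest log2 fold change among genes past the threshold, with a mean CPM of at least 1, no overlap between the groups and a symbol that is not a predicted or clone name. It also named the 3 members of each list with the smallest p, and Havcr1, Lcn2, Slc34a1 and Tlr4, which gave 124 genes, some of which are not reported here. Other list members are given as examples and were chosen after their values were seen. A fold against a group with no counts is a lower bound against a floor of 3 counts over the group's 3 libraries. Ratios with 1 to 3 counts in a group carry an exact 95% binomial interval. Floors and intervals cover counting error only, since the reads carry no molecular identifiers in the sources used here.

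The library totals lay between 29097558 and 33454344 counts. In counts simulated from the Control means of the 14219 genes for LPS against Control, with 200 genes changed, the test recovered 38.8% of genes changed 1.5-fold, 77.6% of those changed 2-fold and 98.5% of those changed 4-fold, and 12 of its 155 calls were unchanged genes.

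The alternatives were RLE factors or library sizes in place of TMM, no low-count filter, a mean CPM of at least 1, DESeq2 1.42.0, limma-voom, limma on log2(FPKM + 1) or log2(FPKM + 0.1), a mean FPKM of at least 1, the replicate number as a block, and leaving out each library in turn. For lists, camera with an estimated correlation and fry were also run. A fit without genes of seminal vesicle names or over 32-fold higher in LPS replicate 2 than in every other library, a fit with library sizes summed without the genes at least 2-fold higher, and a grouping of genes by symbol stem, were chosen after seeing the data.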

Results

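Kidney RNA was compared between 3 mice injected with LPS, a bacterial outer membrane component used to model sepsis, and 3 Control mice injected with saline, 24 h after injection. The question, per the series' design text, was which transcripts differ in kidneys with LPS-induced injury. The LPS libraries held 32257827, 33454344 and 31313181 counts and the Control libraries 29097558, 31071170 and 30608316 counts. Correlations of log2 CPM lay between 0.982 and 0.986 among LPS libraries, between 0.986 and 0.991 among Control libraries and between 0.905 and 0.916 across the groups. All pairs of replicates differed by more than sampling noise, with a chi-square statistic of at least 11.1 per degree of freedom. The first principal component held 81.0% of the variance.

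In LPS kidneys the lists of tubular injury, acute phase and complement, and cytokine and chemokine genes had median log2 fold changes of 2.05, 3.82 and 3.68, and the proximal tubule list had a median of -1.69. All 4 lists passed the list test (camera), and the acute phase list alone of these kept its call with an adjusted p = 0.0466 with an estimated correlation, against an adjusted p = 0.173, 0.203 and 0.167 for the injury, cytokine and proximal tubule lists. Havcr1, which encodes kidney injury molecule 1, rose from 5.65 ± 0.268 CPM to 1456 ± 317 CPM (SD, n = 3 per group), a log2 fold change of 8.01 ± 0.19 (SE). Lcn2, which encodes the neutrophil gelatinase-associated lipocalin, rose from 15.7 ± 1.71 to 3551 ± 836 CPM. The Control counts of both genes were 1.31 and 1.49 times a trace level estimated from other transcripts, so these changes can be lower limits. Slc34a1, the phosphate transporter of the proximal tubule, fell from 5189 ± 560 to 422 ± 29.6 CPM, a log2 fold change of -3.62 ± 0.11. Tlr4, the LPS receptor, did not pass the test, at 6.62 ± 1.22 CPM in Control and 10.6 ± 3.84 CPM in LPS kidneys (edgeR quasi-likelihood test, Benjamini-Hochberg adjusted p = 0.0696). Without LPS replicate 3 its log2 fold change was 0.95 with an adjusted p of 0.00384, and DESeq2 gave an adjusted p of 0.0298, within a range of 0.00384 to 0.205 over all alternatives.

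Of 14219 genes tested, 3658 were higher and 3527 lower in LPS kidneys, together 50.5%. At least 2-fold changes were found for 1171 higher and 1368 lower genes. The groups did not overlap in CPM for 8545 genes (60.1%), where chance gives 10%. Limma on log2(FPKM + 1), a scale that shrinks the change of low genes, gave 687 higher and 655 lower genes at 2-fold or more.

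The 12 largest increases by the naming rule included secreted proteins of the acute phase and chemokines. Saa1 rose by a log2 fold change of 8.52 ± 0.32, Saa2 by 8.49 ± 0.27, Orm2 by 8.26 ± 0.43, the fibrinogen chain Fgb by 8.24 ± 0.32 and the protease inhibitor Serpina3m by 8.13 ± 0.30. The chemokines Cxcl5 and Cxcl1 rose by 8.44 ± 0.32 and 8.01 ± 0.16, and Sult1e1, an estrogen sulfotransferase, by 8.59 ± 0.58. Csf3, the granulocyte colony-stimulating factor, had 1429 counts in LPS and 1 count in Control libraries, a ratio of 1337 (95% interval 240 to 52844). Lypd8 had 1279 and 3 counts, a ratio of 399 (136 to 1937). Tmem145 had 243 counts in LPS and 0 in Control libraries and was at least 75.8-fold higher. The adjusted p of these 12 genes, Havcr1 included, lay between 4.16e-08 and 0.000479 (edgeR). Reads of Saa1 and Saa2, and of other close copies such as Orm1 and Orm2 or the Serpina3 genes, can be split between copies, so their single values are uncertain. The Control counts of all 12 genes were at most 1.31 times the estimated trace level. Their Control levels were not resolved from it, or for Fgb and Havcr1 only in part, and their folds, ratios and SEs can describe lower limits.

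The Control counts of the most induced genes lay close to a trace level estimated from seminal vesicle transcripts, a comparison chosen after the values were seen. LPS replicate 2 carried these transcripts at 3.92% of its counts, and each other library held between 0.0829% and 0.117% of its counts of these genes. The same shares of the 3 LPS libraries would give an expected number of Control counts per gene. The shares were measured for LPS replicate 2 only, and their use for LPS replicates 1 and 3 is an assumption. Of 62 named genes with a log2 fold change above 0, 15 had Control counts under 2 times that number. It is a fixed share of a gene's LPS counts, so genes with the largest folds lie lowest against it by construction. All 12 largest increases were therefore among the 15, which does not show that such a trace reached them. The Control counts were 0.805 times that number for Sult1e1, 0.842 times for Lypd8, 0.928 times for Saa1, 0.941 times for Saa2, 0.947 times for Cxcl5, 1.10 times for Orm2, 1.12 times for Fgb, 1.17 times for Serpina3m, 1.30 times for Cxcl1 and 1.31 times for Havcr1. They were 1.41 times that number for Saa3, 1.49 times for Lcn2 and 1.76 times for Fgg. Csf3 had 1 Control count against 3.98 (a ratio of 0.251, exact 95% Poisson interval 0.00636 to 1.40) and Tmem145 0 against 0.677. The Control levels of these genes were not resolved from such a trace, or only in part for Fgb, Havcr1, Saa3, Lcn2 and Fgg, whose intervals lay above 1, so the folds given for all 15 can be lower limits. Svs4 stood at 10225 unscaled CPM in LPS replicate 2 and at 8.56 to 13.8 CPM elsewhere, and the gene counted among the higher genes with an adjusted p of 0.0207 (edgeR). Without the seminal vesicle genes and others over 32-fold above every other library in LPS replicate 2, a fit chosen after seeing the data, 3646 genes were higher and 3540 lower, 1167 and 1371 of them at least 2-fold. Without LPS replicate 2 the counts were 3142 higher and 3018 lower.

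**Figure D1:**
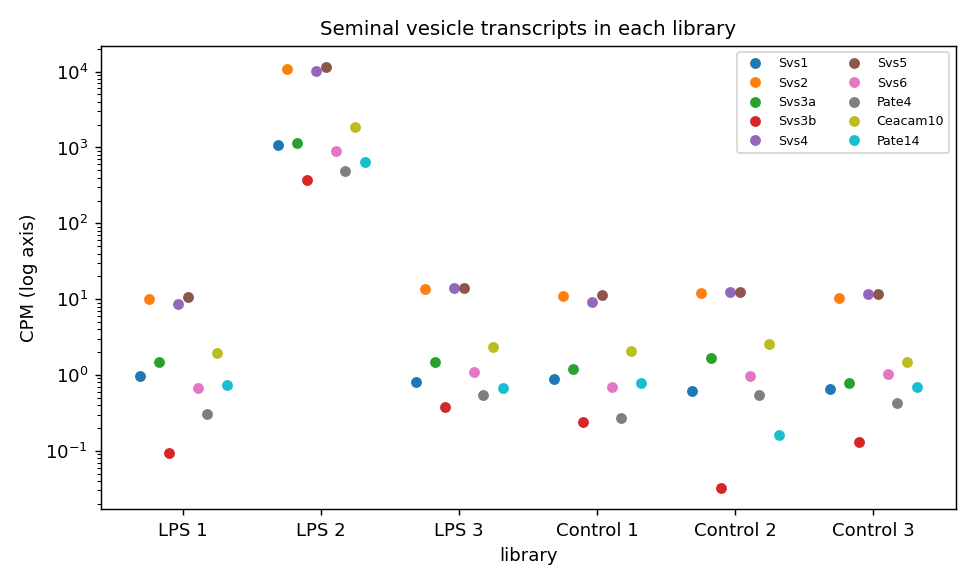
Unscaled CPM (log axis) of 10 seminal vesicle transcripts in each of the 6 libraries, 1 point per gene. All 10 lie highest in LPS replicate 2, where Svs4 reaches 10225 CPM against 8.56 to 13.8 CPM in the other libraries.

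The 12 largest decreases included lectins of myeloid cells and tubular transporters and enzymes. Cd209a, a lectin of dendritic cells, had 268 counts in Control and 0 in LPS libraries and was at least 95.5-fold lower. Mgl2, a macrophage lectin, had 461 counts in Control and 3 in LPS libraries, a ratio of 164 (95% interval 55.9 to 799), and Ccdc170 had 200 and 2 counts, a ratio of 107 (29.2 to 889). Adgrg4 fell by a log2 fold change of -6.30 ± 0.37, Tnn by -6.06 ± 0.46, Trdn by -5.99 ± 0.77, Ldc1 by -5.86 ± 0.23, Pde6a by -5.34 ± 0.27 and Pfn3 by -5.25 ± 0.29. The transporters Slc22a22 and Slc7a13 fell by -5.58 ± 0.18 and -5.49 ± 0.13, and Inmt, a methyltransferase, fell from 1368 ± 104 to 36.5 ± 5.96 CPM. The adjusted p of these 12 genes lay between 4.16e-08 and 0.000276 (edgeR). Some of them differed between Control libraries, though each lay above every LPS library there. Trdn stood at 1.24, 2.90 and 4.51 CPM in Control replicates 1, 2 and 3. Cd209a, Mgl2 and Tnn stood at 4.98, 7.59 and 22.7 CPM in Control replicate 1, against at most 2.05, 4.14 and 11.5 CPM in Control replicates 2 and 3.

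Leaving out 1 library moved the fitted fold of several low-count genes by over 1.5 times. The direction was kept, and so was the call except for Cd79b without Control replicate 1 (log2 fold change -0.66, adjusted p = 0.191, edgeR). The fitted log2 fold change was 11.85 for Csf3 without Control replicate 2 and 8.65 for Tmem145 without LPS replicate 1. Both fits had 0 Control counts, so these 2 values depend on the fit and do not measure a fold. The log2 fold change was 10.01 for Cxcl5 and 8.79 for Serpina3m without Control replicate 1. It was 9.82 for Sult1e1, 9.34 for Lypd8 and 7.76 for Chil3 without Control replicate 3. Among the lower genes it was -8.00 for Mgl2 and -7.18 for Trdn without LPS replicate 2, and -6.99 for Adgrg4 and -4.02 for Upk1a without LPS replicate 1. For Cd209a without Control replicate 1 it was -8.94, a value fitted against 0 LPS counts that does not measure a fold either.

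**Figure D2:**
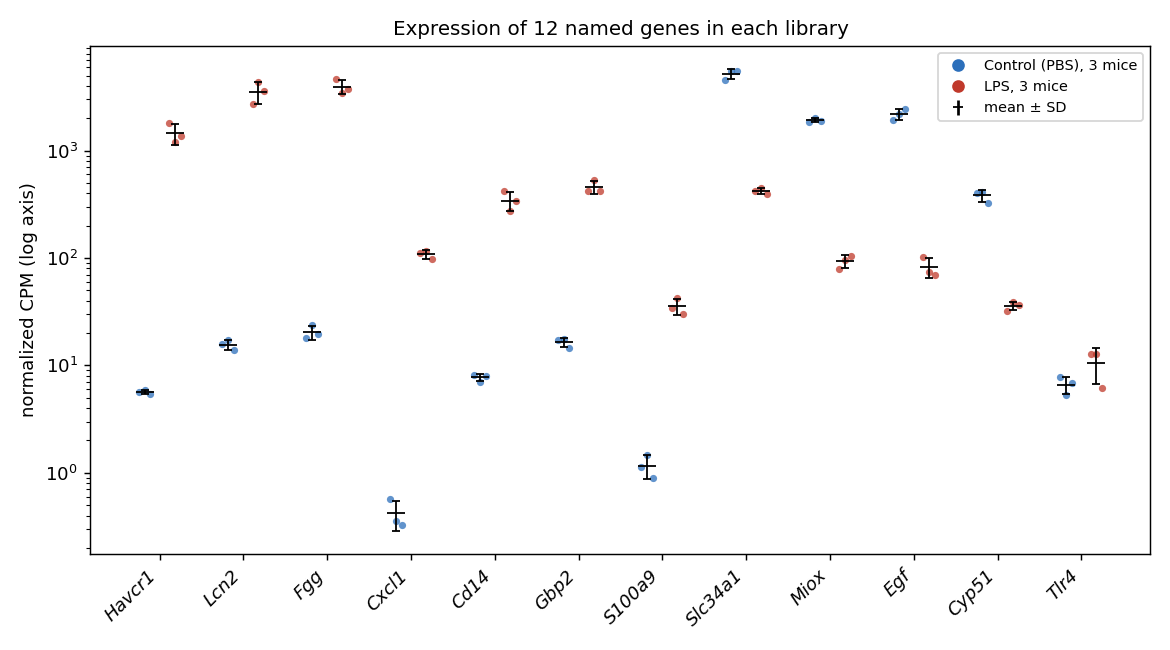
Normalized CPM (log axis) of 12 genes in each library, with Control libraries in blue and LPS libraries in red; points are libraries and black marks give the mean ± SD of 3 mice. The LPS and Control points do not overlap for 11 of the genes, from Havcr1 (5.65 CPM in Control, 1456 CPM in LPS) to Cyp51 (382 and 35.9 CPM), and they overlap for Tlr4.

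Genes of tubular injury, cytokines and chemokines, and toll-like receptor and NF-kB signalling rose together. Of 23 tested injury genes 17 rose and 1 fell (18 and 1 adjusted over the list alone), among them Spp1, which encodes osteopontin, at 33026 ± 5209 CPM in LPS and 960 ± 114 CPM in Control kidneys, and Sox9, with a log2 fold change of 4.93 ± 0.30. Igfbp7 fell by a log2 fold change of -0.35. Of 24 cytokines and chemokines 22 rose and 0 fell (the same adjusted over the list alone), including Il6 (5.98), Ccl2 (5.11), Tnf (3.79) and Csf1 (2.77 ± 0.13), and Il18 (0.01) and Ccl8 (0.50) did not pass. Of 25 receptor and NF-kB genes 24 rose and 0 fell (25 adjusted over the list alone), among them Cd14, the LPS co-receptor, by 5.47 ± 0.17, Bcl3 by 3.11 ± 0.11 and Nfkbia by 2.04 ± 0.08. The list medians were 2.05, 3.68 and 1.44, with camera adjusted p-values of 1.10e-07, 1.51e-10 and 2.75e-11. The calls were lost with an adjusted p = 0.173, 0.203 and 0.203 with an estimated correlation.

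Interferon-stimulated, antigen presentation and acute phase genes were also higher. Of 36 interferon-stimulated genes 33 rose and 0 fell (34 adjusted over the list alone), with Gbp2 and Gbp3, interferon-inducible GTPases, at 4.80 ± 0.14 and 4.64 ± 0.12 and Irgm1 at 2.14 ± 0.09. Rsad2 (-0.08) and Cmpk2 (-0.38) did not pass. Of 21 antigen presentation genes 18 rose and 0 fell (the same adjusted over the list alone), among them the class I genes H2-D1 (2.45 ± 0.08) and H2-K1 (2.36 ± 0.10) and the immunoproteasome subunit Psmb8 (3.01 ± 0.13), and the class II genes H2-Aa (0.27) and H2-Eb1 (0.08) did not pass. Of 24 acute phase and complement genes 21 rose and 0 fell (the same adjusted over the list alone), among them the fibrinogen chains Fgg, from 20.4 ± 3.01 to 3935 ± 598 CPM, and Fga, by 7.07 ± 0.19, and Saa3 by 7.90 ± 0.20. The list medians were 1.77, 1.43 and 3.82, with camera adjusted p-values of 5.59e-13, 3.91e-08 and 1.04e-11. With an estimated correlation the first 2 lists had an adjusted p = 0.235 and 0.267, and the acute phase list kept its call with an adjusted p = 0.0466 with an estimated correlation, the only list of 34 that did.

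Cell death genes and genes of activated endothelium moved in both directions. Of 28 genes of pyroptosis, necroptosis and apoptosis 16 rose and 3 fell (the same adjusted over the list alone), with the necroptosis effector Mlkl at 3.40 ± 0.18, Bcl2l1, an inhibitor of apoptosis, at 1.10 ± 0.10 and Casp8 at 0.93 ± 0.08. Nlrc4 (-0.91) and Bcl2 (-0.45) were among those that fell. Of 22 genes of endothelial activation and coagulation 15 rose and 5 fell (15 and 6 adjusted over the list alone), with the adhesion molecule Icam1 at 3.23 ± 0.15, Lrg1, also a member of the acute phase list, at 6.54 ± 0.32 and Adamts1 at 1.95 ± 0.09, while Angpt2 (-1.50) and Esm1 (-1.75) were among those that fell. The medians were 0.60 and 1.38, with camera adjusted p-values of 0.00211 and 0.00374. These became an adjusted p = 0.216 and 0.344 with an estimated correlation.

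**Figure D3:**
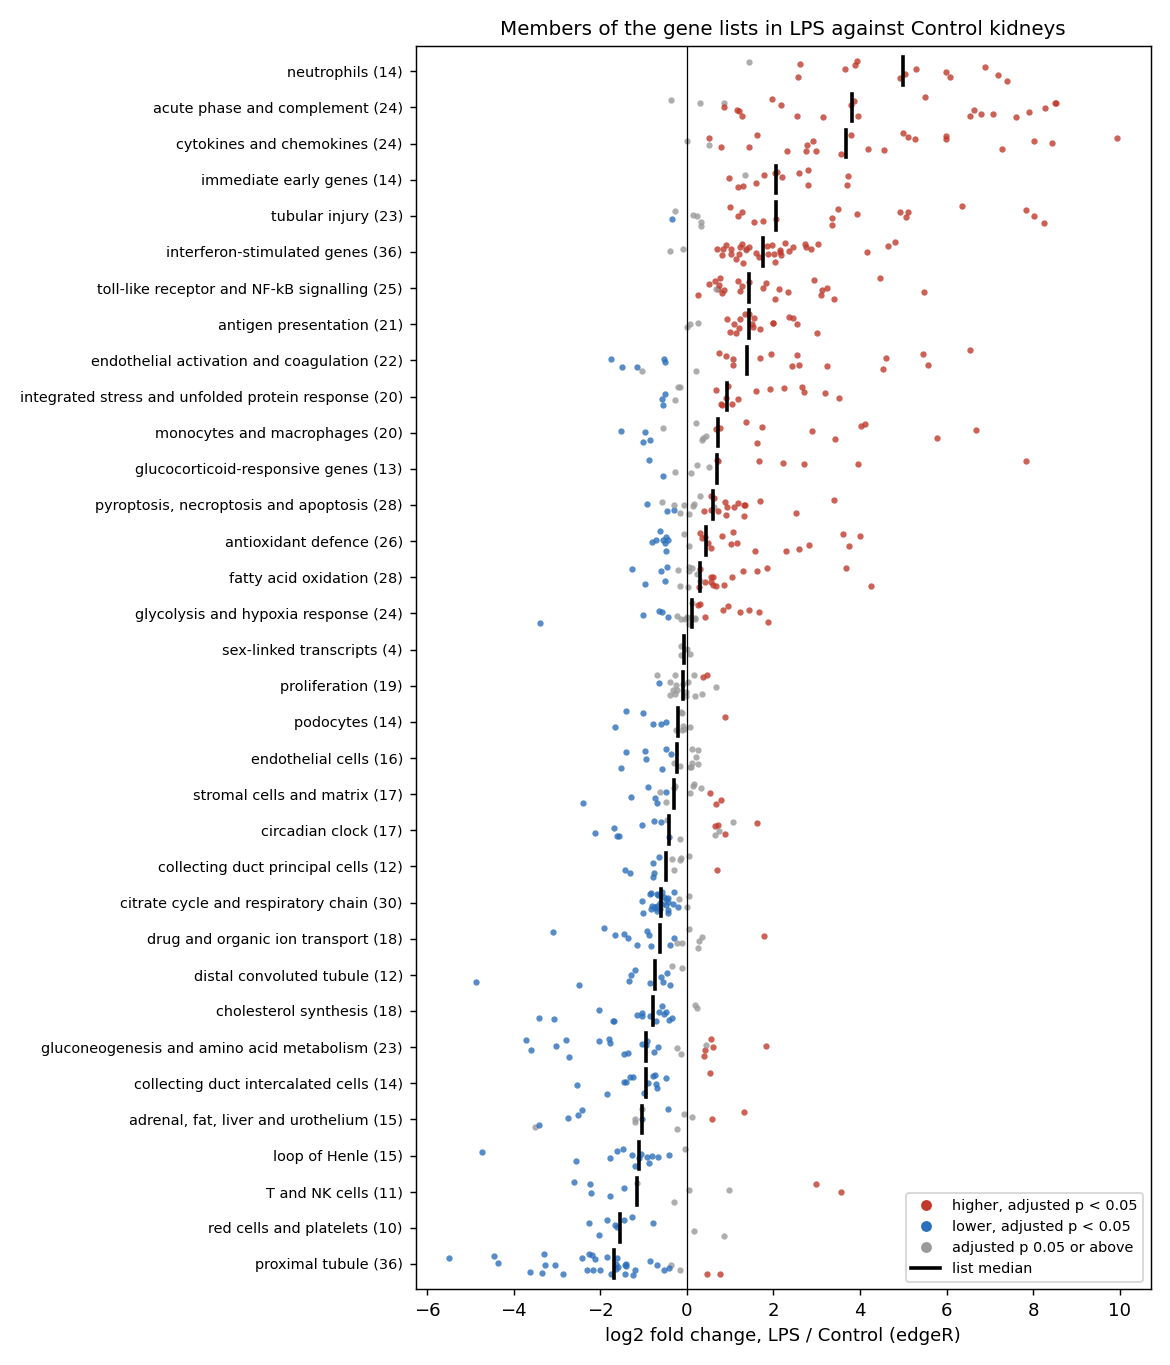
Log2 fold change (LPS over Control) of each tested member of 34 gene lists, 1 point per gene, in red where higher and in blue where lower at an adjusted p under 0.05 and in grey otherwise; black bars are list medians and numbers in parentheses are tested members. Neutrophil genes have the highest median, 4.99, and proximal tubule genes the lowest, -1.69.

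The marker lists of each tubule segment had medians below 0 in LPS kidneys, lowest in the proximal tubule. Of 36 proximal tubule genes 2 rose and 32 fell (33 adjusted over the list alone). Slc7a13, an amino acid transporter, fell from 1323 ± 38.2 to 29.4 ± 4.42 CPM, Miox, the inositol oxygenase, from 1916 ± 84.6 to 93.5 ± 13.2 CPM and Ttc36 by a log2 fold change of -3.29 ± 0.09, while the sulfate transporter Slc13a1 (0.77) and Pck1 (0.46) rose. Of 15 loop of Henle genes 0 rose and 14 fell (the same adjusted over the list alone), with Egf, the epidermal growth factor, at 2181 ± 264 CPM in Control and 81.8 ± 17.3 CPM in LPS kidneys, Ppp1r1b at -1.78 ± 0.09 and Bsnd at -1.61 ± 0.10; Umod, which encodes uromodulin, did not pass (-0.04). Of 12 distal convoluted tubule genes 0 rose and 10 fell (11 adjusted over the list alone), with the calcium-binding Pvalb at -4.87 ± 0.22, Slc8a1 at -2.49 ± 0.18 and S100g at -1.21 ± 0.12. The medians were -1.69, -1.11 and -0.73, with camera adjusted p-values of 3.55e-13, 1.94e-07 and 0.000259. The calls were lost with an adjusted p = 0.167, 0.203 and 0.293 with an estimated correlation.

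In the collecting duct, intercalated cell genes fell in 13 of 14 cases, and principal cell genes in 6 of 12. Among intercalated cell genes 1 rose (the same counts adjusted over the list alone), and Insrr fell by -2.53 ± 0.18, the anion exchanger Slc4a1 by -1.83 ± 0.14 and Slc26a4, which encodes pendrin, by -1.31 ± 0.12. Slc4a1 is also a member of the red cell and platelet list, which had a median of -1.53. Among principal cell genes 1 rose (the same counts adjusted over the list alone), the vasopressin receptor Avpr2 fell by -1.43 ± 0.15, Aqp4 by -1.31 ± 0.15 and Hsd11b2 by -0.77 ± 0.11, and Aqp2 did not pass (-0.13). The medians were -0.95 and -0.49, with camera adjusted p-values of 2.18e-05 and 0.0284, and an adjusted p = 0.240 and 0.344 with an estimated correlation.

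Podocyte, endothelial and stromal markers showed smaller changes. Of 14 podocyte genes 1 rose and 6 fell (the same adjusted over the list alone), with Nphs1, which encodes nephrin, at -1.40 ± 0.10, Tcf21 at -1.66 ± 0.20 and the adaptor Cd2ap at 0.88 ± 0.10. The podocyte median was -0.19, with a camera adjusted p of 0.0477 and an adjusted p = 0.293 with an estimated correlation. That call also ended without LPS replicate 2 (adjusted p = 0.0612), LPS replicate 3 (0.0505), Control replicate 1 (0.0719, median -0.29) or Control replicate 3 (0.0592) and with library sizes as the scaling (0.0520), and over all alternatives the adjusted p ranged from 0.00177 with fry to 0.293. Of 16 endothelial genes 0 rose and 7 fell (the same adjusted over the list alone), with Ehd3 at -1.41 ± 0.09, Ptprb at -1.51 ± 0.13 and Tek at -0.95 ± 0.10. The list did not pass (median -0.23, camera adjusted p = 0.103) except without Control replicate 3 (adjusted p = 0.0468) and in fry (0.0464), in a range up to 0.639 over the alternatives. Of 17 stromal and matrix genes 3 rose and 6 fell (3 and 7 adjusted over the list alone), with Tgfb1 at 0.79 ± 0.10, Rgs5 at -0.89 ± 0.14 and Lum at -2.40 ± 0.51, and the list did not pass (median -0.29, camera adjusted p = 0.452).

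Neutrophil genes were higher and monocyte and macrophage genes moved in both directions. Of 14 neutrophil genes 13 rose and 0 fell (14 adjusted over the list alone), with the calprotectin subunits S100a8 and S100a9 at 5.04 ± 0.22 and 4.93 ± 0.20 and Trem1 at 5.29 ± 0.45. List members below the count filter were not tested: Ly6g had 4 and 2 counts in LPS and Control libraries, Elane 4 and 0, Mpo 6 and 0 and Camp 96 and 2. The median was 4.99, or 4.63 with Stfa2l1, at 64 counts in LPS and 0 in Control libraries, set to its lower bound, a log2 fold change of 4.32. Of 20 monocyte and macrophage genes 11 rose and 4 fell (the same adjusted over the list alone), with Chil3 at 6.69 ± 0.40, Plac8 at 4.01 ± 0.14 and Cd68 at 2.88 ± 0.18, while the receptors Csf1r (-0.85), Ccr2 (-1.52), Cx3cr1 (-1.01) and Mrc1 (-0.98) fell. That median was 0.71, and the camera adjusted p-values of both lists were 3.91e-08 and 0.0119, with an adjusted p = 0.174 and 0.461 with an estimated correlation.

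Of 11 T and NK cell genes 2 rose and 5 fell (the same adjusted over the list alone), and the list did not pass (median -1.14, camera adjusted p = 0.442). The granzymes Gzma and Gzmb rose by 2.99 ± 0.49 and 3.57 ± 0.61, and Cd8a fell by -1.45 ± 0.31, Cd3d by -2.61 ± 0.56 and Cd4 by -2.23 ± 0.69. Only 2 B cell genes were tested, and both fell (the same adjusted over the list alone), Jchain by -1.87 ± 0.36 and Cd79b by -1.35 ± 0.49. Control replicate 1 stood apart in B cell genes, with Cd79a at 2.47 CPM against 0.423 and 0.263 CPM in the other Control libraries. Without that library Cd79b did not pass (log2 fold change -0.66, adjusted p = 0.191, edgeR) and neither did Cd4 (-1.60, adjusted p = 0.0872) or Cd8b1 (-1.19, adjusted p = 0.156). Cd79b also missed the threshold without LPS replicate 1 (adjusted p = 0.0510), LPS replicate 2 (0.116) or LPS replicate 3 (0.0932), within a range of 0.0179 to 0.191 over all alternatives.

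Of 10 red cell and platelet genes 0 rose and 8 fell (1 and 8 adjusted over the list alone), with the haemoglobin genes Hba-a2 at -1.61 ± 0.23 and Hbb-bs at -1.65 ± 0.25, near copies of Hba-a1 and Hbb-bt. The median was -1.53, with a camera adjusted p of 0.0112 and an adjusted p = 0.371 with an estimated correlation. Of 15 markers of adrenal gland, fat, liver and urothelium 2 rose and 6 fell (the same adjusted over the list alone), among them the uroplakins Upk1a (-3.42 ± 0.37), Upk3a (-2.75 ± 0.34) and Upk2 (-2.42 ± 0.31). That list did not pass (median -1.04, camera adjusted p = 0.0980), except without Control replicate 1 (median -1.53, adjusted p = 0.0202) and in fry (0.0483), in a range up to 0.461 over the alternatives. Fat transcripts differed between Control libraries: Adipoq, which encodes adiponectin, stood at 7.69 CPM in Control replicate 1 and at 24.6 and 37.3 CPM in the others, against 2.23 to 5.71 CPM in LPS libraries.

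Among metabolic genes, the lists of the citrate cycle and respiratory chain, cholesterol synthesis, amino acid metabolism and organic ion transport had medians below 0. Of 30 citrate cycle and respiratory chain genes 0 rose and 27 fell (the same adjusted over the list alone), by small amounts, with Ndufs1 at -1.03 ± 0.08, Sdhb at -1.01 ± 0.09 and Atp5o at -0.81 ± 0.07. Of 18 cholesterol synthesis genes 0 rose and 16 fell (the same adjusted over the list alone), with Cyp51 from 382 ± 50.8 to 35.9 ± 3.41 CPM, Idi1 at -3.07 ± 0.11 and Insig1 at -2.02 ± 0.09. Of 23 genes of gluconeogenesis and amino acid metabolism 5 rose and 15 fell (5 and 16 adjusted over the list alone), with Hgd at -2.03 ± 0.09 and Prodh2 at -2.79 ± 0.14. Of 18 drug and organic ion transporters 1 rose and 11 fell (the same adjusted over the list alone), with Slco1a1 at -3.10 ± 0.15, Slc47a1 at -1.92 ± 0.11 and Slc22a2 at -1.45 ± 0.09. The medians were -0.60, -0.78, -0.95 and -0.61, with camera adjusted p-values of 8.34e-09, 2.77e-06, 0.000670 and 0.00435. The calls were lost with an adjusted p = 0.344, 0.167, 0.344 and 0.235 with an estimated correlation.

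Fatty acid oxidation genes moved in both directions, with a median of 0.30. Of 28 members 15 rose and 5 fell (the same adjusted over the list alone). Pdk4, a kinase that inhibits pyruvate dehydrogenase, rose by 3.69 and the carnitine carrier Slc25a20 by 1.30 ± 0.10, while the acyl-CoA dehydrogenase Acadm fell by -1.27 ± 0.08. The camera adjusted p was 0.0180, with an adjusted p = 0.461 with an estimated correlation. Of 24 glycolysis and hypoxia genes 9 rose and 5 fell (10 and 6 adjusted over the list alone), with Hk2 at 1.88 ± 0.19, Eno1 at 0.96 ± 0.09 and Car9 at -3.38 ± 0.33, and the list did not pass (median 0.13, camera adjusted p = 0.348) except in fry (adjusted p = 0.00748), in a range up to 0.461 over the alternatives.

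Immediate early genes were higher, and antioxidant and stress response genes moved in both directions. Of 26 antioxidant genes 16 rose and 8 fell (the same adjusted over the list alone), with the metallothioneins Mt2 and Mt1 at 3.75 ± 0.09 and 2.82 ± 0.10 and the haem oxygenase Hmox1 at 3.62 ± 0.15, while Sod1 (-0.62) and Cat (-0.56) fell. Of 20 genes of the integrated stress and unfolded protein responses 14 rose and 3 fell (14 and 4 adjusted over the list alone), with Ddit3 at 1.92 ± 0.10, Atf5 at 1.60 ± 0.10 and Asns at 2.70 ± 0.25, and the heat shock genes Hspa1a (-0.55), Hspa1b (-0.50) and Hsph1 (-0.57) fell. Of 14 immediate early genes 13 rose and 0 fell (the same adjusted over the list alone), with Junb at 2.80 ± 0.09, Myc at 2.60 ± 0.10 and Jun at 2.03 ± 0.12. The medians were 0.45, 0.92 and 2.06, with camera adjusted p-values of 0.0180, 0.00265 and 3.91e-08, and an adjusted p = 0.384, 0.344 and 0.203 with an estimated correlation.

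Glucocorticoid-responsive genes had a median of 0.70, and clock, proliferation and sex-linked lists did not pass. Of 13 glucocorticoid-responsive genes 7 rose and 2 fell (the same adjusted over the list alone), with Cebpd at 3.94 ± 0.11 and Map3k6 at 2.71 ± 0.20, while Tsc22d3 (-0.54) and the receptor gene Nr3c1 (-0.87) fell. Lcn2 belongs to that list and to the injury list. The camera adjusted p was 0.0322, with an adjusted p = 0.461 with an estimated correlation, and without Control replicate 1 it was 0.0644, in a range of 0.000992 to 0.461 over the alternatives. Of 17 clock genes 4 rose and 8 fell (the same adjusted over the list alone), with Hlf at -1.68 ± 0.18, Per3 at -1.61 ± 0.19 and Tef at -1.03 ± 0.14 (median -0.41, camera adjusted p = 0.516). Of 19 proliferation genes 2 rose and 1 fell (the same adjusted over the list alone), Mcm2 at 0.46 ± 0.11, Pcna at 0.38 ± 0.09 and Mcm6 at -0.63 ± 0.09 (median -0.09, camera adjusted p = 0.688). The 4 Y-linked genes were expressed in all 6 libraries and 0 passed (also adjusted over the list alone), with Ddx3y at 56.7 ± 2.01 and 61.9 ± 4.91 CPM in LPS and Control kidneys, Uty at 33.5 ± 5.16 and 36.5 ± 1.35 CPM and Eif2s3y at 46.1 ± 8.84 and 43.6 ± 1.76 CPM (median -0.05, camera adjusted p = 0.715). Without LPS replicate 1 Uty passed the test with a log2 fold change of -0.25 (adjusted p = 0.0412, edgeR), in a range up to 0.850 over the alternatives.

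Camera with its preset correlation called 26 of 34 lists, 15 up and 11 down, and with an estimated correlation 1. In fry, which asks whether a list's genes move on balance one way and does not compare lists, 29 passed. The mitochondrially encoded genes of another list were not analysed here.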

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

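Fits that left out seminal vesicle and replicate-specific genes were chosen after seeing the data. The 4 counts of higher and lower genes stayed within 1.5 times of their values under every alternative except limma on log2(FPKM + 1), where genes at least 2-fold higher numbered 687 and genes at least 2-fold lower 655, or 652 and 646 with a mean FPKM of at least 1; an added 1 pulls the fold of low genes toward 0. Leaving out 1 library, which also leaves fewer samples, gave 3054 to 3629 higher and 2994 to 3463 lower genes. DESeq2 gave 3604 and 3581, with 14 genes left without an adjusted p. Of the 7185 calls 7129 were called in the same direction with RLE factors and 7061 with library sizes, scalings that hardly differed from TMM here. The number of lists called was 1 with an estimated correlation in place of 26, and 25 to 26 without 1 library; that setting lets members that move together count as fewer independent genes. Of 2099 values of named genes under the alternatives 2088 kept direction and side of the threshold, 8 lost the call, all of Cd79b, and 3 gained one, for Tlr4 and Uty. Of 442 list values 406 were kept, 31 lost and 5 gained a call, and 0 values of either kind reversed. The replicate numbers gave no sign of paired mice: deviations of same-numbered libraries correlated at 0.0478, -0.0535 and -0.00201, not every library correlated best with its own number, and with the number as a block 3414 genes were higher and 3331 lower, 1157 and 1361 at least 2-fold, and 26 lists were called. In simulated LPS against Control data the test recovered 38.8% of genes changed 1.5-fold. Few genes were changed there and 155 were called, against 7185 here, and the adjusted threshold is stricter with fewer calls. That share therefore does not measure how many 1.5-fold changes were found in the real data. Smaller changes passed there, as in 42 of 49 genes named Rpl, with a median log2 fold change of 0.37.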

Other observations

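The grouping of genes by symbol stem, the tests of T cell genes and of counts taken by induced genes, and the first 2 tests of the seminal vesicle transcripts were chosen after the results were seen. Among 235 families of at least 8 tested genes that share a symbol stem, camera called 26, and 0 with an estimated correlation (adjusted p = 0.911 for all 26). Of 49 genes named Rpl, which encode proteins of the large ribosomal subunit, 42 rose and 0 fell, with a median log2 fold change of 0.37 (camera adjusted p = 9.97e-07), and of 43 genes named Rps 26 rose and 2 fell, a stem that also holds kinases such as Rps6ka5 (-0.97). Regulatory proteasome subunits (Psmd) rose in 12 of 14 cases with a median of 0.62 (camera adjusted p = 0.00118), among them Psmd11 at 0.99 ± 0.08. The medians of these families had the same sign with RLE factors and with library sizes. These scalings hardly differed from TMM here, so the kept signs are no test of the medians.

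Carboxylesterases (Ces) fell in 7 of 9 cases with a median of -2.76 (camera adjusted p = 0.00547), among them Ces1d at -3.11 ± 0.14 and Ces2b at -3.19 ± 0.25, and some are close copies whose reads can be split. Carbonic anhydrases (Car) fell in 9 of 13 cases, with Car14 at -3.78 ± 0.17 and Car4 at -3.08 ± 0.16, while Car13 rose by 2.52 ± 0.17 (median -1.13, camera adjusted p = 0.0176). Car3 fell by -4.82, but stood at 73.0, 204 and 269 CPM in Control replicates 1, 2 and 3, in the same order as the fat transcript Adipoq. Axonemal dynein heavy chains (Dnah), motors of motile cilia, fell in 7 of 10 cases with a median of -1.58 (camera adjusted p = 0.0266). All these medians kept their sign with RLE factors and with library sizes, which for the same reason is no test of them.

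Of the 10 splits of the 6 libraries into 3 and 3, the real one gave 7185 genes past the threshold and the highest of the others 0 (edgeR; 62 to 267 genes at an unadjusted p under 0.05, against 8069). The real split was the only 1 of 10 as large, and 10 splits are too few for a share under 0.05.

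Seminal vesicle transcripts made up 3.92% of the counts of LPS replicate 2. All 9 genes with seminal vesicle names lay at least 100-fold above every other library there, and their median log2 ratio of LPS replicates 1 and 3 to Control was 0.0792 (SD 0.250), which argues against a kidney response to LPS. Seminal vesicle RNA in that library is a candidate source that stays open, since these genes are the ones that raised it. The traces elsewhere may come in part from reads of that library, but 1 of 779 genes, Svs3b, had under 0.5 of the Control counts that a fixed passed-on share predicts (12 against 34.9 counts, one-sided exact Poisson test, adjusted p = 0.00565), which argues against such a share as the whole source. Svs3b is a close copy of Svs3a, which was at 1.03 times its prediction, Svs1 was at 0.642 times (adjusted p = 0.0307), and no gene outside the seminal vesicle set was under 0.5.

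Proximal tubule genes fell with a median of -1.69. A smaller share of proximal tubule RNA alone would leave the distal segments at or above 0, but the 4 distal lists pooled had a median of -0.86 (95% bootstrap interval -1.19 to -0.71), and the members' log2 fold changes had an SD of 1.36. Counts taken by induced genes, as the whole source, were argued against by a median of -1.48 (95% bootstrap interval -1.99 to -1.20) with library sizes summed without the 1171 genes at least 2-fold higher, which held 17.1% of LPS and 3.26% of Control counts. TMM, RLE and library-size scaling hardly differed here and decide nothing on this. Bootstrap intervals here and below resample the genes of the lists, not the mice. They take the genes as independent and do not measure the spread between mice. Lower expression per cell along the whole tubule, or loss of cells in all segments, may each contribute, as hypotheses that were not tested.

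Neutrophil and some macrophage markers rose. More red cell RNA in the LPS kidneys was argued against by the 4 haemoglobin genes, some of them near copies, with a median of -1.63. This argues against more blood only if haemoglobin RNA per volume of blood was unchanged, which was not tested. Leukocytes in the blood were not measured by it. A larger share of T cells, or of leukocytes of every kind, stays open. Cd3d, Cd3g and Cd8a, 3 of 5 receptor and coreceptor genes, were lower with all libraries and without Control replicate 1, but only 1 of these, Cd8a, had a mean of at least 1 CPM, the granzymes Gzma and Gzmb rose, and the median of the T and NK cell list, -1.14, had a 95% bootstrap interval of -2.21 to 0.96 that includes 0. More neutrophils, or higher expression per cell, may account for the rise, as hypotheses that were not tested.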
